A study of Mus musculus with 8 samples.

How the data were processed

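Bulk RNA sequencing was carried out on haematopoietic stem cells (HSCs) from the bone marrow of mice that carry a GFP-LC3 reporter, in which green fluorescent protein is fused to LC3, a protein of the autophagosome membrane that is degraded as autophagy proceeds. Per the labels, 2 libraries came from unfractionated HSCs of young mice aged 8 to 12 weeks, and 6 came from 3 old mice aged over 24 months. Per the labels, the HSCs of old mice were sorted into the 33% with the lowest GFP signal (AThi, autophagy-high) and the 33% with the highest (ATlo, autophagy-low). Per the labels' protocols, RNA came from about 10000 HSCs with an RNA integrity number over 9.0 and was collected on 2 sort days. All low-input libraries were prepared together, per the labels' protocols, and read as paired ends of 50 bases to a target of 40 M reads. The sources used here do not say which library belongs to which sort day.

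Per the submitters' processing notes, FastQC, MultiQC, STAR, featureCounts and DESeq2 were used with the mouse build GRCm38; their order, versions, gene annotation and strand setting are not given in the sources used here. The authors' deposited tables hold, for each of 3 contrasts and 19909 genes, a log2 fold change with its standard error, a Wald statistic (score), a p-value and an adjusted p-value, and a base mean signal; 73 genes had no p-value. The same tables hold 8 columns of a normalized signal per library, identical in all 3, which per the file headers carry the group and a tag (D11 and D12 for young, O10, O11 and O12 for each old fraction). These columns were matched to groups only, because the tags are not the replicate numbers of the labels. Another of the authors' deposited tables lists 726 upstream regulators for AThi against ATlo with an activation score, a p-value of overlap and the log2 fold change of the regulator; the program that made it is not given in the sources used here. The score of 1 regulator is not reported here.

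The normalized signal that the authors deposited is a read count divided by 1 factor per library. Dividing each column by the value of 1 read gave whole reads, within 0.01 of a read, for 100% of values in each library. The recovered totals were 45590508 and 44021141 reads for the young libraries, 33960216, 40498336 and 45830216 for AThi, and 57714738, 54512285 and 61341946 for ATlo. The ribosomal RNA genes mt-Rnr1, mt-Rnr2 and Rn18s took between 27.1% and 36.1% of the reads. No pair of libraries within a group agreed within sampling noise (chi-square over degrees of freedom between 52.9 and 109). Depths cover counting error only, since reads without molecular identifiers are not independent molecules.

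The differences in log2 fold change between the 2 contrasts against young equalled the AThi against ATlo value within 1.1e-14, so the 3 tables come from 1 fit without shrinkage. The ratio of shared variance was 0.599, against 0.6 for a fit of 8 libraries without a term for the mouse. The main test is therefore the authors' deposited DESeq2 Wald test with Benjamini-Hochberg adjustment, with a gene called at an adjusted p below 0.05. The design written before the data were examined named edgeR for the case that a file held counts in place of contrasts. The tables held contrasts together with a normalized signal, so the deposited test was kept and edgeR on the recovered reads was run as an alternative. Recovered reads were refitted with DESeq2 1.42.0 and with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Other steps used limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

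Both fits were tested on simulated data for AThi against ATlo, with the means, library factors and dispersions of the 19909 genes and 200 genes changed, in 5 simulations for each source of dispersion. With each gene's own dispersion, DESeq2 recovered 59% to 72% of the genes changed by 1 on the log2 scale and 89% to 95% of those changed by 2, and edgeR recovered 33% to 48% and 72% to 90%. DESeq2 made 51 to 77 false calls, which were 24.2% to 32.6% of its calls, and edgeR made 2 to 8, or 1.72% to 6.67%. With dispersions from the fitted trend, DESeq2 made 27 to 60 false calls, or 15.3% to 28.8%, and edgeR 1 to 10. In these simulations, with 200 genes changed, the adjusted p of 0.05 thus admitted more false calls than its nominal rate in the DESeq2 fit at these group sizes. The share of false calls depends on how many genes change, so it does not carry over to the real contrasts.

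The same design fixed 24 gene lists, 9 lists of cell type markers and the rule for named genes. The rule takes, per contrast, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a base mean of 100 or more (13611 genes in all) and a symbol that is not a predicted, clone, mitochondrial or pseudogene name. It adds up to 4 members of each list by adjusted p, 11 genes of the gate and question whatever their p, and up to 10 genes called in all 3 contrasts. Lists were tested with cameraPR of limma on the Wald statistic, two-sided, with a preset correlation between genes of 0.01 and adjustment over the 33 lists of a contrast. Members without a p-value took no part in this test. For called named genes with 10 or fewer reads in a group, an exact (Clopper-Pearson) 95% interval of the ratio of reads was taken, which covers counting error only. In a simulation of 10000 genes with independent statistics, a planted list of 40 genes had an adjusted p of 4.9e-10 and 0 of 33 random lists were called. Since these genes were not correlated, the simulation does not test the preset correlation. The estimated correlation was taken with camera on voom values of the recovered reads. That run thus also changed the gene statistic and took in members without a p-value, and it held no term for the tag. A further 8 families were chosen by symbol after the data were seen.

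Per the labels, the 2 fractions of an old mouse are paired, and equal column tags were taken as the pairs after a check. Deviations from the group mean of AThi and ATlo libraries with the same tag correlated across genes at 0.209, 0.164 and 0.373, so a replicate block for the tag was fitted as an alternative. AThi O12 and ATlo O12 also correlated in this way with young D12, from another mouse, at 0.184 and 0.182. The value of 0.373 for O12 is thus not a measure of the shared mouse alone. For the lists the block was run first with voom. The block with the DESeq2 statistic was added after those results had been seen, because it keeps the kind of statistic of the main test. Each block was fitted to the old libraries alone. Both are reported. The other alternatives were the threshold, a minimum fold change, the set of genes adjusted, centring of fold changes, and leaving out each library. Chosen after the data were seen were edgeR on the recovered reads, the estimated correlation, a term for the tag 12, leaving out the libraries tagged 12, the split of the young libraries between the contrasts, and thinning of all libraries to the shallowest. Gene coordinates come from the GENCODE vM21 annotation of GRCm38, matched by Ensembl identifier. Per-library levels are normalized counts given as mean ± SD. Since strand is not given, reads of overlapping antisense genes cannot be told apart.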

Results

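The series asked how the transcriptome differs between HSCs of old mice that engage autophagy and those that do not, and how each compares with young HSCs. Libraries came from 2 young samples, 3 old AThi samples and 3 old ATlo samples. Depth was 44021141 and 45590508 reads in young, 33960216, 40498336 and 45830216 in AThi, and 54512285, 57714738 and 61341946 in ATlo libraries, so ATlo libraries were the deepest.

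Cells with the lowest GFP-LC3 signal carried less mRNA of the cell cycle than their ATlo partners from the same mice. Of 50 genes of S phase, 40 were lower and 0 higher in AThi, and of 49 genes of G2 and M phase, 44 were lower and 0 higher. Pclaf, a partner of the replication clamp PCNA, was at 486 ± 47.4 normalized counts in AThi (SD, n = 3) against 2320 ± 94.3 in ATlo (SD, n = 3) and 1441 ± 105 in young (SD, n = 2). Top2a, the DNA topoisomerase of dividing cells (chromosome 11, 98992943 to 99024189), was at 14811 ± 776 in AThi and 36697 ± 2950 in ATlo (SD, n = 3 each). Of 46 stem cell identity genes, 11 were higher and 1 lower in AThi (edgeR called 6 higher, and adjusted p = 0.025 with an estimated correlation). Of 54 genes of the old HSC signature, 16 were higher and 0 lower (edgeR called 6 higher, and adjusted p = 0.093 with an estimated correlation).

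In the authors' deposited table, 1414 genes passed the adjusted p of 0.05 in AThi against ATlo, 621 higher and 793 lower, out of 17908 genes with an adjusted p. The strongest by adjusted p in the authors' deposited table was Pclaf (log2 fold change -2.25, SE 0.15, adjusted p 1.9e-45; chromosome 9, 65890237 to 65903266, GRCm38). The ribonucleotide reductase subunit Rrm1 had a log2 fold change of -1.24 (SE 0.10) in the authors' deposited table, the replication licensing gene Mcm5 of -1.80 (SE 0.16) and the transcription factor E2f1 of -2.16 (SE 0.23). Mki67, a marker of proliferating cells, fell by 1.42 (SE 0.17, adjusted p 2.1e-13) in the authors' deposited table. Further falls in the authors' deposited table were those of Slc1a4, a neutral amino acid transporter (log2 fold change -4.17, SE 0.77), Aunip (-3.43, SE 0.51), Chtf18 (-2.47, SE 0.51), Ung (-2.30, SE 0.23) and Spc24 (-2.27, SE 0.40). Among the largest rises in the authors' deposited table were Thbs1, which encodes thrombospondin 1 (log2 fold change 3.46, SE 0.75), Shroom2 (3.25, SE 0.67), Mmp28 (3.18, SE 0.78) and Ppargc1a, a coactivator of mitochondrial biogenesis (3.07, SE 0.62). Thbs1 was uneven in AThi, at 138 ± 139 normalized counts against 12.6 ± 6.83 in ATlo (SD, n = 3 each). Its AThi mean lay below that of young (331 ± 111, SD, n = 2).

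**Figure D1:**
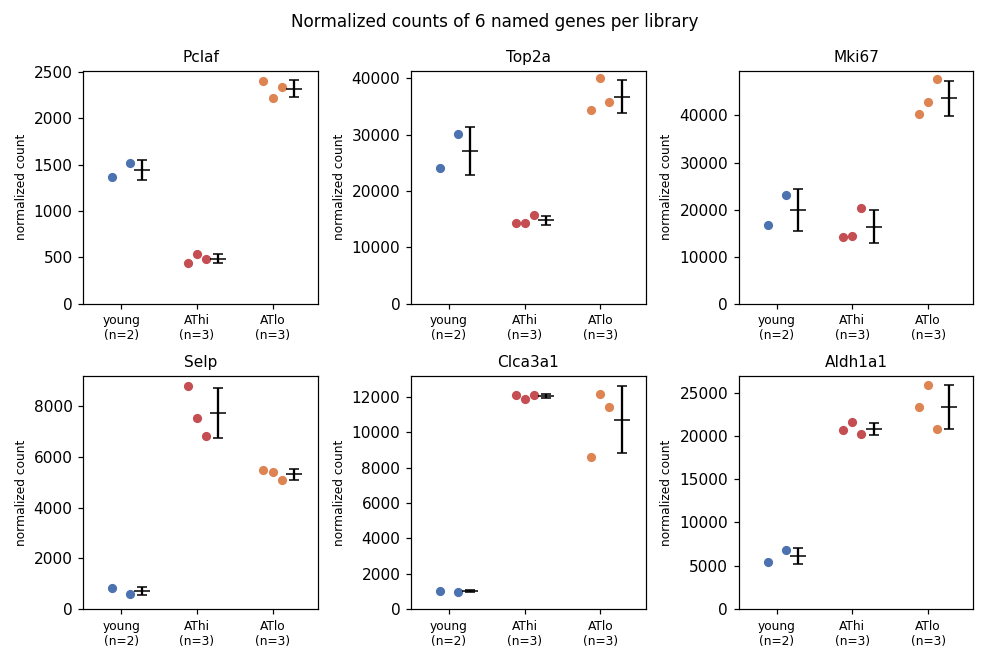
Normalized counts of Pclaf, Top2a, Mki67, Selp, Clca3a1 and Aldh1a1 in each library (points, linear axes from 0), with the mean and SD of the young (n = 2), AThi (n = 3) and ATlo (n = 3) groups as bars. Pclaf lay between 441 and 535 in the AThi libraries and between 2217 and 2401 in the ATlo libraries.

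The S phase list was lower in AThi (adjusted p 1.5e-92; 47 of 50 members lower when adjusted over the list alone). So was the G2 and M phase list (adjusted p 3.0e-92; 47 of 49 adjusted over the list alone). Both calls held with an estimated correlation (adjusted p = 0.025 for each). Oxidative phosphorylation genes were lower, with 23 of 74 members lower and 0 higher, and 35 lower adjusted over the list alone (adjusted p 8.4e-18, and adjusted p = 0.013 with an estimated correlation). The edgeR test called 2 of the 74 lower. The ATP synthase subunit Atp5g3 had a log2 fold change of -0.69 (SE 0.11) in the authors' deposited table and the cytochrome oxidase subunit Cox7b of -0.62 (SE 0.12). Stem cell identity genes were higher (11 of 46 higher and 1 lower, 13 higher adjusted over the list alone, adjusted p 1.0e-06, and adjusted p = 0.025 with an estimated correlation). Procr, a surface marker of HSCs, had a log2 fold change of 0.95 (SE 0.18) in the authors' deposited table, Rarb, a retinoic acid receptor, of 1.31 (SE 0.27) and Runx1 of 0.41 (SE 0.09).

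Several lists passed with the preset correlation and not with an estimated one. FoxO factors and targets were higher (6 of 35 members, adjusted p 1.3e-05; adjusted p = 0.054 with an estimated correlation), among them S1pr1, Klf6, Sesn3 and Txnip. The old HSC signature was higher (16 of 54, adjusted p 6.4e-11; adjusted p = 0.093 with an estimated correlation), led by Gda, Jam2, Gpr183 and Exoc6b. Autophagy machinery was higher with 4 of 52 members called (adjusted p 0.010; adjusted p = 0.080 with an estimated correlation); these were Trp53inp1, Atg16l2, Tecpr1 and Rb1cc1, with edgeR adjusted p of 0.098, 0.11, 0.15 and 0.14. The LC3 genes Map1lc3b and Map1lc3a, Gabarapl1 and the receptor Sqstm1 had log2 fold changes in the authors' deposited table of 0.19 (SE 0.11), -0.60 (SE 0.62), 0.28 (SE 0.17) and 0.27 (SE 0.17), with adjusted p of 0.38, 0.68, 0.37 and 0.41. JAK-STAT feedback (4 of 29 higher), immediate early genes (6 of 40), interferon response (4 of 51), TNF and NF-kappaB targets (3 of 36) and TGF-beta and SMAD genes (1 of 27) were higher with adjusted p of 0.0061, 0.0081, 0.0029, 0.013 and 0.026. With an estimated correlation these had adjusted p = 0.080, adjusted p = 0.071, adjusted p = 0.57, adjusted p = 0.16 and adjusted p = 0.42. Heat shock proteins (3 of 22 lower), tricarboxylic acid cycle genes (1 of 25), the mTORC1, AKT and MYC list (7 of 35) and unfolded protein response genes (3 of 38) were lower with adjusted p of 0.0060, 0.0037, 0.026 and 0.021. With an estimated correlation these had adjusted p = 0.57, adjusted p = 0.054, adjusted p = 0.36 and adjusted p = 0.57. Without the 3 libraries tagged 12, the TNF and NF-kappaB, TGF-beta and SMAD, and mTORC1, AKT and MYC lists were not called (adjusted p 0.11, 0.16 and 0.055). Autophagy machinery was not called without the ATlo library tagged O10 (adjusted p 0.056), nor was interferon response without the AThi library tagged O11 (adjusted p 0.21).

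With the preset correlation and no replicate block, no list of another cell type was called in AThi against ATlo: megakaryocyte and platelet, erythroid, granulocyte, monocyte, B, T and NK, mast cell, stromal and multipotent progenitor markers had adjusted p between 0.095 and 0.81. Members without a p-value in the authors' deposited table took no part, which left out 6 of 10 B cell genes (with Ighm and Cd79a), 4 of 14 erythroid, 2 of 11 T and NK and 2 of 17 progenitor genes (Mpo and Car1). The granulocyte, monocyte and stromal lists each lacked 1 gene. Without the 3 libraries tagged 12, the granulocyte list was higher and the progenitor list lower (adjusted p 0.036 for each). Without ATlo O12 the granulocyte and B cell lists were higher (adjusted p 0.022 and 0.014), and without AThi O11, AThi O12 or ATlo O10 the progenitor list was lower (adjusted p 0.034, 0.0049 and 0.022). With the replicate block and the DESeq2 statistic, the multipotent progenitor list, which shares Mki67 with the cell cycle, was lower in AThi (adjusted p 0.020). With the block in voom it was not called (adjusted p 0.19), while the B cell list was higher (adjusted p 0.0034) and the erythroid list lower (adjusted p 0.045). The median log2(normalized count + 1) of the B cell list was 9.66 in AThi O12, 9.13 in ATlo O12 and at most 4.13 in the other old libraries. Without ATlo O12, AThi O12 was thus the only old library with a high level. Which libraries carried the call with the block in voom was not tested. Lysosome, quiescence, glycolysis, hypoxia, antioxidant, ribosomal protein, cholesterol and fatty acid oxidation lists were not called (adjusted p between 0.16 and 0.81), except lysosome genes without AThi O12 (higher, adjusted p 0.035) and ribosomal proteins without AThi O11 (lower, adjusted p 0.038). For the hypoxia list the median and the mean statistic differed in sign. Socs3, Foxo3, Slc2a1 and Clu had log2 fold changes in the authors' deposited table of 0.87 (SE 0.36), 0.10 (SE 0.14), 0.10 (SE 0.23) and -0.08 (SE 0.54), with adjusted p of 0.13, 0.80, 0.89 and 0.97, and Txnip and Selp rose by 0.77 (SE 0.20) and 0.54 (SE 0.15), with edgeR adjusted p of 0.11 for each.

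**Figure D2:**
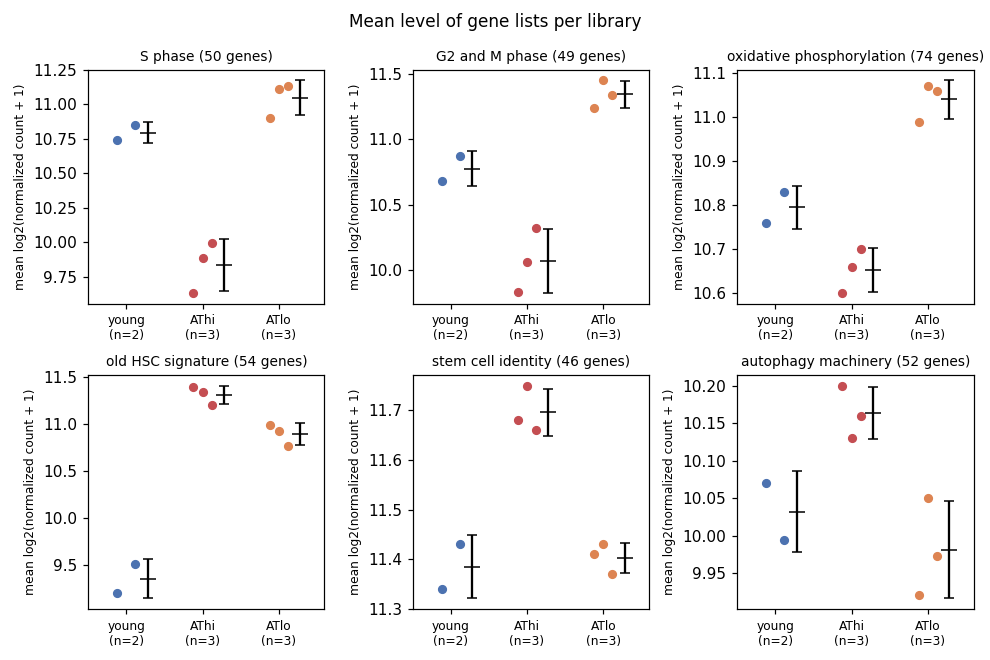
Mean log2(normalized count + 1) over the members of 6 gene lists in each library (points), with the mean and SD of the young (n = 2), AThi (n = 3) and ATlo (n = 3) groups as bars; axes do not start at 0. The S phase list averaged 9.84 ± 0.19 in AThi and 11.05 ± 0.13 in ATlo, and the old HSC signature 9.36 ± 0.21 in young, 11.32 ± 0.09 in AThi and 10.90 ± 0.11 in ATlo.

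The edgeR quasi-likelihood test on the recovered reads called 280 genes in this contrast, 60 higher and 220 lower, all 280 of them also called in the authors' deposited table in the same direction. The share of higher calls moved from 621 of 1414 to 60 of 280. Of the 97 genes called under the naming rule, 62 were not called by edgeR. Thbs1, Shroom2, Mmp28, Ppargc1a and Slc1a4 were among these (edgeR adjusted p 0.081, 0.055, 0.13, 0.072 and 0.055). In simulated data the DESeq2 fit made 51 to 77 false calls, and without the ATlo library tagged O11 the count fell to 932.

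AThi HSCs had higher levels of genes of the old HSC signature, a list of genes raised in aged HSCs that was not chosen on these samples, than young HSCs. Of 54 measured signature genes, 43 were higher and 1 lower. The chloride channel regulator Clca3a1 (chromosome 3, 144729677 to 144760977, GRCm38) was at 12046 ± 115 normalized counts in AThi (SD, n = 3) and 1015 ± 46.0 in young (SD, n = 2), and Selp, the adhesion receptor P-selectin, at 7713 ± 982 against 714 ± 159. Cell cycle genes were lower than in young, with 31 of 50 S phase and 26 of 49 G2 and M phase genes lower and 0 higher in either. By edgeR 17 and 2 of these genes were lower, and the lists had adjusted p = 0.051 and adjusted p = 0.11 with an estimated correlation. Old cells were gated on GFP and young HSCs were unfractionated, so gate and age cannot be told apart in either contrast against young.

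In AThi against young, 961 genes passed in the authors' deposited table, 596 higher and 365 lower. Clca3a1 rose by 3.57 on the log2 scale (SE 0.16, adjusted p 6.2e-103) and Selp by 3.43 (SE 0.18, adjusted p 2.3e-81) in the authors' deposited table. Among the largest rises in the authors' deposited table were the potassium channel gene Kcnb2 (log2 fold change 9.38, SE 1.13), Limch1 (7.37, SE 0.95), the oncostatin M receptor Osmr (6.54, SE 0.54), Zg16 (6.37, SE 0.57), Cdh4 (6.16, SE 0.65), the metallothionein Mt2 (5.56, SE 0.62) and the mucin Muc1 (5.28, SE 0.42). The sizes of some are loosely set, since the 2 young libraries together held 2 reads of Kcnb2, 4 of Limch1 and 9 of Zg16. Their log2 ratios of reads had exact 95% counting intervals of 7.47 to 12.37, 6.02 to 9.26 and 5.46 to 7.52. Among the falls in the authors' deposited table were Rgs7bp (log2 fold change -5.58, SE 0.57), Slc1a4 (-4.14, SE 0.85), Skint3 (-3.33, SE 0.65) and Nrk (-2.43, SE 0.29). Clu, encoding clusterin, and Socs3, an inhibitor of cytokine signalling, rose by 2.62 (SE 0.60) and 1.92 (SE 0.41) in the authors' deposited table. By contrast in the authors' deposited table, Map1lc3b, Mki67, Txnip and Foxo3 had log2 fold changes of 0.32, -0.29, 0.37 and -0.37 with adjusted p of 0.15, 0.58, 0.49 and 0.21.

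The signature was called with an adjusted p of 1.5e-165 (48 higher adjusted over the list alone). Stem cell identity was called at 2.6e-06, with 8 of 46 higher and 1 lower (edgeR called 4 higher). With an estimated correlation these lists had adjusted p = 0.020 and adjusted p = 0.032. Megakaryocyte and platelet genes were higher (9 of 21, and 5 by edgeR, adjusted p 7.0e-24, and adjusted p = 0.079 with an estimated correlation). Selp, Vwf, Cavin2, Itgb3 and Itga2b of that list also stand in the signature. S phase (adjusted p 1.4e-53, 40 lower adjusted over the list alone) and G2 and M phase (adjusted p 2.3e-25, 37 lower adjusted over the list alone) were lower; with an estimated correlation they had adjusted p = 0.051 and adjusted p = 0.11. Lysosome (5 of 50 higher, 1 lower), JAK-STAT feedback (5 of 29), TGF-beta and SMAD (2 of 27), quiescence (2 of 31 higher, 2 lower) and granulocyte genes (2 of 14, Prtn3 and Csf3r) were higher with adjusted p of 0.0085, 0.0066, 0.036, 0.036 and 0.012. With an estimated correlation they had adjusted p = 0.18, adjusted p = 0.19, adjusted p = 0.44, adjusted p = 0.15 and adjusted p = 0.44. The quiescence list, as fixed, also holds the cell cycle drivers Cdk6, Ccnd1, Ccnd2 and Ccnd3, so its direction is not a measure of quiescence. Oxidative phosphorylation (1 of 74 lower) and multipotent progenitor genes (Flt3 and Cd34, 2 of 17 lower) were lower with adjusted p of 0.0066 and 0.032, and with an estimated correlation adjusted p = 0.16 and adjusted p = 0.37. Without the 3 libraries tagged 12, 17 lists were called in place of 12 and the quiescence list was not (adjusted p 0.089). The young arm was then D11 alone, the only library with female levels of Xist, and its spread was assumed to be that of the other groups. The calls gained in that comparison with 1 sample were antioxidant, cholesterol, ribosomal protein and T and NK genes (higher, adjusted p 0.019, 1.0e-04, 0.028 and 0.027), heat shock proteins and the mTORC1, AKT and MYC list (lower, adjusted p 0.028 and 0.027). They do not separate age from that sample. The remaining lists were not called with all libraries, and the median and mean statistic differed in sign for the erythroid (median log2 fold change -0.67), hypoxia, unfolded protein, monocyte and fatty acid oxidation lists. The edgeR test called 240 genes, 168 higher and 72 lower. It did not call 51 of the 91 genes called under the naming rule, among them Slc1a4, Clu and Socs3 (edgeR adjusted p 0.073, 0.055 and 0.076). Without the young library tagged D12 the count in the DESeq2 fit was 585.

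ATlo HSCs carried the signature as well, with 34 of 54 genes higher and 0 lower than in young (edgeR called 21 higher). Aldh1a1, a retinaldehyde dehydrogenase, was at 23338 ± 2541 normalized counts in ATlo (SD, n = 3) and 6142 ± 924 in young (SD, n = 2). Mki67 was at 43599 ± 3799 in ATlo and 19988 ± 4474 in young. Of 49 G2 and M phase genes, 14 were higher and 0 lower, edgeR called 1 of the 49 higher, and the list had adjusted p = 0.14 with an estimated correlation.

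In ATlo against young, 811 genes passed in the authors' deposited table, 442 higher and 369 lower. Clca3a1 rose in the authors' deposited table by 3.40 (SE 0.16, adjusted p 2.0e-93), Selp by 2.89 (SE 0.18, adjusted p 3.1e-57), Aldh1a1 by 1.93 (SE 0.14) and Mki67 by 1.13 (SE 0.19, adjusted p 1.1e-06). Among the largest changes in the authors' deposited table were the rises of Kcnb2 (log2 fold change 7.84, SE 1.13), Zg16 (6.45, SE 0.57), Mt2 (6.22, SE 0.62) and Osmr (5.30, SE 0.54) and the falls of Rgs7bp (-5.40, SE 0.56), Thbs1 (-4.72, SE 0.83), Socs2 (-4.49, SE 1.23), Plxdc2 (-3.07, SE 0.27) and Hoxa3 (-2.87, SE 0.53). With 2 young reads of Kcnb2 and 9 of Zg16, the exact 95% counting intervals of the log2 ratios were 5.99 to 10.89 and 5.52 to 7.58.

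The signature had an adjusted p of 2.3e-102 (42 higher adjusted over the list alone) and oxidative phosphorylation (2 of 74 higher) of 7.1e-07; with an estimated correlation both had adjusted p = 0.035. G2 and M phase (26 higher adjusted over the list alone), S phase (1 of 50 higher, Rfc5) and megakaryocyte and platelet genes (11 of 21 higher, 1 lower, and 4 higher by edgeR) were higher with adjusted p of 2.9e-18, 5.0e-04 and 1.6e-21. With an estimated correlation they had adjusted p = 0.14, adjusted p = 0.45 and adjusted p = 0.14. Antioxidant (2 of 34, Mt1 and Mt2), glycolysis (3 of 40, with Ldha, Slc16a1 and Tpi1) and unfolded protein response genes (4 of 38 higher, 3 lower) were higher with adjusted p of 0.0020, 0.038 and 0.039, and with an estimated correlation adjusted p = 0.61, adjusted p = 0.44 and adjusted p = 0.66. Autophagy machinery was not called as a list (1 of 52 higher, 4 lower, adjusted p 0.50). The median and mean statistic differed in sign for the erythroid, JAK-STAT, TGF-beta, stem cell identity, quiescence, hypoxia and stromal lists. None of these was called. Without the 3 libraries tagged 12, which again left the female D11 as the young arm with a spread taken from the other groups, 10 lists were called in place of 8. The glycolysis list was not called (adjusted p 0.059). Calls gained against that 1 sample were cholesterol and ribosomal protein genes (higher, adjusted p 1.7e-05 and 0.019) and FoxO factors and targets (lower, adjusted p 0.048), and the cholesterol list was also called without D12 alone (adjusted p 1.4e-04). The edgeR test called 130 genes, 93 higher and 37 lower. It did not call 64 of the 91 genes called under the naming rule, among them Thbs1, Socs2 and Hoxa3 (edgeR adjusted p 0.059, 0.095 and 0.071). Without the young library tagged D11 the DESeq2 count was 362 and 4 lists were called.

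The 2 contrasts against young shared 359 called genes, of which 291 were higher in both and 54 lower in both. Another 14 were lower in AThi and higher in ATlo and 0 the other way. Independent lists of these sizes over 18678 genes would share 14.1 higher and 7.17 lower genes, and 100 simulated draws of unchanged groups with the shared young libraries, over 19836 genes, gave 0 shared calls. The draws took the Wald statistic as normal. Under that assumption unchanged groups give almost no calls at this threshold, so the number of shared calls was near 0 by construction. The covariance of log2 fold changes was 0.549, against 0.362 from the shared libraries alone, and the correlation across genes, which are not independent replicates, was 0.619 against 0.605. With the young libraries split, D11 for AThi and D12 for ATlo, 159 calls were shared (143 higher and 15 lower in both) and the covariance was 0.294. The reverse split gave 188 (162 higher and 11 lower in both) and 0.286, and independent lists would share 6.33 or 9.65 higher and 0.724 or 1.61 lower genes. Each split leaves 1 young library per contrast, which is assumed to vary like the other groups, so part of the excess in the full comparison may come from the shared controls. The old fractions also came from the same mice, and their libraries of the same tag deviated together (correlations of 0.209, 0.164 and 0.373). AThi O12 and ATlo O12 also deviated together with young D12 (0.184 and 0.182), so mouse and tag cannot be told apart there. None of these comparisons removes the part shared by old libraries of the same tag. Genes lower in AThi and higher in ATlo numbered 0 in the first split and 15 in the reverse. Of the 14 genes of opposite direction with all libraries, 9 were in the G2 and M phase list, among them Top2a, Cdk1 and Ccna2, 0 in the S phase list and 5 in neither. Genes called in all 3 contrasts numbered 53.

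The authors' deposited table of upstream regulators for AThi against ATlo gave an activation score to 350 of 726 regulators, 62 of them at 2 or more and 88 at -2 or less. The lowest scores in the authors' deposited table were those of CEBPB (-7.69), CSF2 (-6.17) and TBX2 (-5.65). The drivers of proliferation MYC, FOXM1 and E2F1 were at -4.98, -4.64 and -3.99 in the authors' deposited table. Among the highest scores in the authors' deposited table were NUPR1 (6.82), let-7 (5.64, marked as biased) and CDKN2A (5.18), with the inhibitors of the cell cycle CDKN1A at 4.54 and RB1 at 3.96, and FOXO3 at 2.61. The regulators' own log2 fold changes in the authors' deposited table were -0.34 for CDKN1A, opposite in sign to its score, 0.18 for RB1, 0.10 for FOXO3, 0.69 for NUPR1 and 0.04 for CEBPB. They were -0.25 for MYC, -1.36 for FOXM1 and -2.16 for E2F1 in the authors' deposited table, in which 43 regulators were marked as biased.

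Libraries also differed in ways that the groups do not explain. The X-inactivation transcript Xist was at 97743 normalized counts in the young library tagged D11, in which the Y-linked gene Ddx3y was at 4.16, while Ddx3y was between 1918 and 3219 in the other 7. The 3 libraries whose tag ends in 12, 1 in each group, carried Xist at 3869 (young), 5810 (AThi) and 2747 (ATlo), against at most 171 in the remaining male libraries. The B cell immunoglobulin gene Ighm was at 8395, 20936 and 7314 in the same 3 libraries and at most 63.5 elsewhere, and the haemoglobin gene Hba-a1 at 700.1, 255 and 485 against at most 16.6. With the 3 libraries left out, the DESeq2 fit called 793, 582 and 482 genes in the 3 contrasts, with the female D11 as the 1 young library left, and 635, 448 and 326 of them were among the authors' calls.

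**Figure D3:**
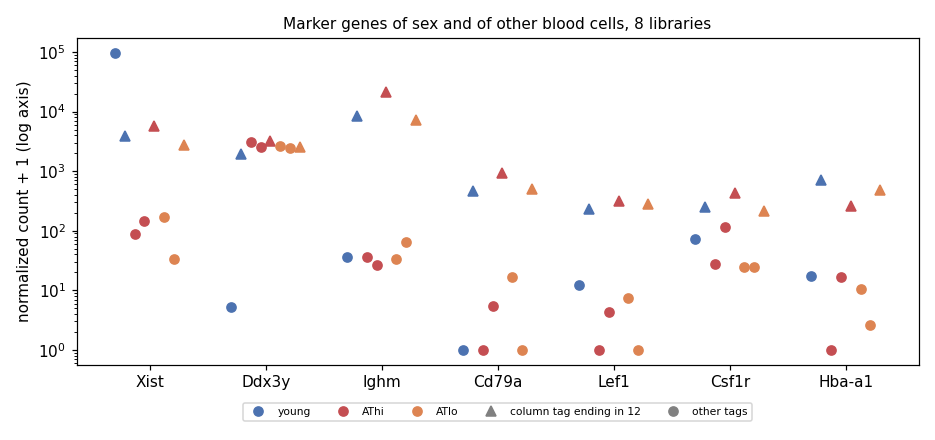
Normalized count + 1 (log axis) of Xist, Ddx3y, Ighm, Cd79a, Lef1, Csf1r and Hba-a1 in the 8 libraries, coloured by group; triangles are the 3 libraries with a column tag ending in 12 and circles the other 5. Ighm was at 7314 or more in the triangles and at 63.5 or less in the circles.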

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

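The tests by thinning, the trend removal with the replicate block, the progenitor list without Mki67, the splits of the old libraries, the split of the young libraries, the sex of a young library, platelet markers, the libraries tagged 12 and edgeR were chosen after the results they bear on had been seen.

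Genes and lists were picked out here because they were called in opposite directions against young in the 2 old fractions. AThi against ATlo equals the difference of those 2 contrasts, so for these genes it restates the selection. In the authors' deposited table the differences in log2 fold change were -1.38 for Birc5, -1.14 for Bub1b, -1.43 for Ccna2, -1.48 for Cdk1, -0.77 for H2az1, -1.50 for Kif14 and -1.71 for Nuf2. The authors' deposited table gave -1.38 for Nusap1, -2.25 for Pclaf, -1.36 for Prc1, -0.93 for Tfdp1, -1.38 for Tk1, -1.31 for Top2a and -1.24 for Tpx2. The lists of oxidative phosphorylation, S phase and G2 and M phase did the same, with a difference in mean Wald statistic in AThi against ATlo of -2.21, -5.74 and -5.76 in that order. With an estimated correlation, the lists had adjusted p = 0.16, adjusted p = 0.051 and adjusted p = 0.11 in AThi against young. In ATlo against young they had adjusted p = 0.035, adjusted p = 0.45 and adjusted p = 0.14 with an estimated correlation, and without young D11 the S phase list had an adjusted p of 0.068. The opposite calls of genes against young rest on the deposited test: for Pclaf, edgeR gave an adjusted p of 0.0031 in AThi and 0.12 in ATlo. With the young libraries split, the genes lower in AThi and higher in ATlo numbered 0 or 15, depending on which library went to which contrast.

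Lower cell cycle genes in AThi than in ATlo may reflect a difference in cycling between the fractions, which is a hypothesis. Of 84 members of the 2 lists called lower, 83 were still called lower when all libraries were thinned to the shallowest. In that fit with the replicate block 84 were. Thinning leaves each expected ratio as it was and evens only the counting noise. The calls thus did not need the deeper reads of ATlo, but a bias tied to depth and already in the counts would remain after thinning. After removal of the trend on GC content and transcript length over 11890 genes, the median log2 fold change of the lists was -1.21, against -1.21 before. The 95% bootstrap interval of the median after removal, taken over member genes, was -1.28 to -1.14. With the replicate block the median after removal was -1.24. Genes of a list are not independent replicates, so the interval does not cover the spread between animals. Progenitors in the ATlo gate stay open, although an HSC sort would normally remove them. The progenitor list without Mki67 had an adjusted p of 0.547 (14 members, since Mpo and Car1 had no p-value), 0.589 on 16 members with the replicate block and 0.717 on 16 without the libraries tagged 12. Whether a small share of cycling cells would move these markers was not tested. Of the 10 splits of the 6 old libraries, 1 (the real one, 1414 genes) called as many genes, the highest of the others called 76, and those that also part all 3 pairs called 3, 10 and 28; 10 splits are too few for a share under 0.05.

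The old HSC signature was higher in both old fractions than in young. The sex of the young library tagged D11 is a candidate explanation. Without that library the median log2 fold change of the signature in AThi against young was 1.60, against 1.64 with it. The young arm was then D12 alone, a library tagged 12 with Ighm at 8395 normalized counts. The signature thus also rose against D12, but that arm has no replicate and carries reads of other blood cells. Platelets or megakaryocytes stay open. The median of 16 megakaryocyte and platelet markers outside the signature was 0.422 in AThi (95% bootstrap interval over the markers -0.0368 to 1.03), below the signature median of 1.64. Such an interval resamples genes and does not cover the spread between animals. The upper end of that interval was not below 0.82, the bound set for ruling them out. In ATlo the median of these markers was 0.75 (0.233 to 1.25), where the signature median was 1.17. In young, AThi and ATlo (SD, n = 2, 3 and 3), Pf4 was at 679 ± 52.8, 904 ± 344 and 1774 ± 867 normalized counts. Ppbp was at 82.5 ± 40.2, 19.9 ± 25.1 and 44.5 ± 54.7, and its fall was not called in the authors' deposited test (adjusted p 0.65 and 0.89). Of these markers, Plek, F2r, Cd9 and Gp1ba were called higher in AThi against young and none lower. In ATlo against young, Plek, Cd9, Pf4, Gp1ba, Gp9 and Gp1bb were called higher and Thbs1 lower. The age of the mice stays open as an explanation and was not tested apart from these.

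The libraries tagged 12 may hold cells of other types, in part from a female animal. In 9 of 9 combinations of a marker list (B, T and NK, monocyte) and a group, the library tagged 12 had the highest median in its group, but the lists hold 9 of the genes that drew attention to these libraries, so the count restates the observation (without those 9 genes it was 9 of 9 as well). Xist was 3.96%, 5.94% and 2.81% of the level in the young library tagged D11. Mixed-in cells stay open, although an HSC sort would normally remove them. Ighm, Cd79a and Hba-a1 were at most 63.5, 15.7 and 16.6 in the libraries not tagged 12. For these genes, though not for Xist, this argues against a carry-over of RNA or reads from those libraries. A carry-over among the libraries tagged 12, or from a source outside the series, stays open and was not tested. Such libraries were 1 of 2 in young and 1 of 3 in each old fraction, with Ighm at 8395, 20936 and 7314, so the contrasts against young are not balanced in number nor AThi against ATlo in load, and no biological explanation was tested.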

How the results depend on the processing

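The alternatives with edgeR, a term for the tag 12, the libraries tagged 12 left out, thinning, the split of the young libraries and an estimated correlation were chosen after the data were seen. No named gene that was called turned its direction under the alternatives compared here. No list was called in opposite directions by the main test and one of these alternatives. A list that turned its direction and lost its call was not counted apart from other lost calls. For AThi against ATlo, AThi against young and ATlo against young, the counts were 784, 603 and 420 at a threshold of 0.01, 651, 592 and 512 with an absolute log2 fold change of 1 or more as well, and 180, 221 and 177 with a Wald test against 0.5, which by construction ask for more. The edgeR test gave 280, 240 and 130, with a term for the tag 12 it gave 317, 237 and 148, and with the libraries tagged 12 left out DESeq2 gave 793, 582 and 482 from fewer samples, with the female D11 alone as the young arm; why the tools differ was not tested beyond the simulations. Leaving out 1 library gave 932 to 1422, 585 to 1093 and 362 to 894 genes, lowest without ATlo O11, young D12 and young D11. A lone young library was assumed to vary like the other groups. In DESeq2 with all libraries, a term for the tag 12 gave 1647, 1040 and 943 genes.

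With the replicate block, fitted to the old libraries alone, AThi against ATlo gave 1954 genes in DESeq2 (939 higher, 1015 lower) and 303 in edgeR. An unplanned DESeq2 fit of the old libraries alone without the block gave 1356 genes. For the lists, the block with the DESeq2 statistic added the call of multipotent progenitor genes (lower, adjusted p 0.020), and the block with voom added lymphoid B (higher, adjusted p 0.0034) and erythroid genes (lower, adjusted p 0.045) and not the progenitors (adjusted p 0.19); neither ended a list call.

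The lists called were 16, 12 and 8. They fell to 6, 5 and 4 with a preset correlation of 0.05 and to 5, 4 and 3 with 0.1, so that most list calls depend on that setting. With an estimated correlation 4, 2 and 2 lists were called. That run also used voom values in place of the Wald statistic, so its lost calls cannot be credited to the correlation alone. Leaving out 1 library gave 13 to 17, 10 to 17 and 4 to 10 lists, and without young D11 the S phase, antioxidant, glycolysis and unfolded protein lists lost their call in ATlo against young (adjusted p 0.068, 0.065, 0.16 and 0.73). In AThi against ATlo, 7 lists lost their call when at least 1 library was left out. Autophagy machinery did so without ATlo O10 (adjusted p 0.056), interferon response without AThi O11 (0.21) or ATlo O10 (0.066), and heat shock proteins without AThi O11 (0.051) or ATlo O12 (0.22). The TNF and NF-kappaB list did so without AThi O12 (0.091) or ATlo O10 (0.083), the unfolded protein list without AThi O10 (0.17) or ATlo O12 (0.11), and the TGF-beta and mTORC1 lists without several. With the libraries tagged 12 left out, 15, 17 and 10 lists were called. Leaving out 1 library also gave calls to 5, 11 and 5 lists that had none with all libraries. In AThi against young, the lysosome, TGF-beta, quiescence, granulocyte and progenitor lists lost theirs without at least 1 library. With a term for the tag 12, 16, 13 and 9 lists were called. That term ended the quiescence call in AThi against young (adjusted p 0.064) and added FoxO and T and NK genes there (higher, adjusted p 0.045 and 0.048). In ATlo against young it added FoxO genes (lower, adjusted p 0.044). The 359 genes shared by the contrasts against young became 222 at a threshold of 0.01 and 93 with edgeR, and 223 to 346 when 1 library was left out, lowest without young D11. They became 159 and 188 with the 2 young libraries split between the contrasts, in which fewer samples take part. Regulators with a score of 2 or more in size numbered 150, and 51 at 3 or more. For named genes, 8305 of the values under alternatives kept their side of the threshold, 1103 lost and 151 gained a call; the cause was not tested. With all libraries thinned to the shallowest, AThi against ATlo, AThi against young and ATlo against young gave 1390, 922 and 752 genes. Each group had only 2 or 3 libraries, and the effect of more animals was not tested.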

Other observations

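The gene families in this part and the tests of them were chosen by symbol after the data were seen. Replication-dependent histone genes, which supply histones during S phase, were lower in AThi than in ATlo in 44 of 64 members and higher in 0, with a median log2 fold change of -1.26 in the authors' deposited table. The list test gave an adjusted p of 3.8e-46, and adjusted p = 0.079 with an estimated correlation. Tubulins (7 of 14 lower), splicing factors (15 of 34), proteasome subunits (8 of 40) and mitochondrial ribosomal proteins (8 of 83) were lower too, with adjusted p of 1.1e-15, 2.8e-14, 2.0e-10 and 4.7e-07. With an estimated correlation they had adjusted p = 0.031, adjusted p = 0.031, adjusted p = 0.031 and adjusted p = 0.026.

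The list of 13 proteins encoded by mitochondrial DNA was not called in AThi against ATlo (adjusted p 0.46), while nuclear genes of oxidative phosphorylation were lower. Whether the 2 sets differ was not tested. Clustered protocadherins were higher in AThi in 4 of 35 members (adjusted p 7.4e-05; adjusted p = 0.061 with an estimated correlation) and MHC genes in 1 of 29 (adjusted p 0.016; adjusted p = 0.16 with an estimated correlation). Against young, the MHC genes were higher in AThi in 4 of 29 members (adjusted p 1.4e-05; adjusted p = 0.089 with an estimated correlation).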
